A study of Mus musculus with 7 samples.

How the data were processed

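RNA sequencing of mouse lung was analyzed in 7 libraries, 3 labelled tumors of EZH2-overexpressing mice, 2 labelled normal lung of EZH2-overexpressing mice and 2 labelled wild-type lung. Each deposited file held 22474 rows with a gene symbol and an FPKM value, which the authors made with TopHat2 or TopHat and Cufflinks 2.0.0 on the mouse build mm9, per the submitters' processing notes. The unit was read from the named tool and from the values, since the file headers give only sample names. The annotation, the library normalization option, the strand setting and the read totals are not given in the sources used here. The labels' growth text describes culture of minced tumor nodules and of human cell lines while the source is given as lung tissue, so whether the RNA came from tissue or from cultured nodules is not stated. In each file 27 rows carried a date in place of a gene symbol and were left out, which left 22447 genes with unique symbols. No coordinates were used, because the files carry none and the reference available was of another build.

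Groups were taken from the labels, and the comparisons, fixed lists and main alternatives were chosen before the data were examined. Values were transformed to log2(FPKM + 1) without further scaling, and the 14057 genes with at least 1 FPKM in at least 2 of the 7 libraries were tested. Linear models were fitted with limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend, 2-sided, Benjamini-Hochberg adjusted p under 0.05), with all 7 libraries in 3 groups sharing 1 estimate of the spread. Tumors were also compared with the 4 normal lungs together in a 2-group fit. The median SE of a log2 difference was 0.19 between tumors and either normal group and 0.21 between OE normal and WT lung. Named genes followed a fixed rule. It took the 6 highest and 6 lowest log2 differences among calls with non-overlapping groups and a higher mean of at least 5 FPKM, up to 4 called members per list or 2 where none was called, and Ezh2. Where fewer than 10 genes passed, it took the 10 genes with the smallest unadjusted p under the same conditions of non-overlap and mean. Some genes that the rule named are not reported.

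There were 31 fixed gene lists, of which 30 had at least 5 members tested. They covered PRC2 subunits, cell cycle, alveolar type 2 and type 1, club, ciliated, basal and squamous, neuroendocrine, gastrointestinal, lung lineage and fetal regulators, endothelial, fibroblast, smooth muscle, heart, mesothelium, adipocyte, macrophage, neutrophil, T and NK cell, B and plasma cell, MHC class II, erythroid, interferon response, ERK output, insulin and IGF, developmental PRC2 targets, genes reported as repressed by EZH2, glycolysis, ribosome biogenesis, immediate early and sex-linked genes. Each list was tested with camera from limma at a preset correlation of 0.01 and again with an estimated correlation, and its members were counted at the threshold over all genes and adjusted over the list alone. Of 38 developmental PRC2 targets 29 were below the expression minimum, as were 8 basal and squamous genes.

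Read depth was compared through the spacing of low values. The ratio shared by the most low-expressed genes between each library and tumor 1 gave relative depths of 1.72 and 1.27 for tumors 2 and 3, 1.20 and 1.87 for the OE normal lungs and 1.46 and 1.37 for the WT lungs. FPKM summed to 405166 to 503550 per library, of which small RNA genes held 5.80% to 16.7%. Sex was read from Xist and Eif2s3y. Tumor 1, OE normal 1 and both WT lungs had Eif2s3y between 27.4 and 30.7 FPKM, and tumors 2 and 3 and OE normal 2 had Xist between 60.6 and 74.2 FPKM. Of 87 genes with at least 1000 FPKM in some library, small RNA genes left out, 2 (Sftpc and Scgb1a1) were listed at 0 in another. For these 2 genes values are given per library without a fold.

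The procedure was tested on simulated data with 200 of 14057 genes changed in each of 5 runs. It recovered 46.6%, 91.0% and 96.3% of genes changed 2-fold, 4-fold and 8-fold for tumors against OE normal lung, and 47.9%, 88.0% and 97.6% for tumors against WT lung. For tumors against all normal lung it recovered 73.1%, 92.8% and 98.2%, and 4.88% to 5.36% of calls were false across comparisons. The simulated genes varied independently, with the spread that limma estimated and equal in all groups. The real data need not follow this, so these rates may not hold for them. Comparisons that share libraries were set beside 50 simulations of unchanged groups for covariances and 20 for overlaps. Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios scaling, rescaling to TPM, quantile normalization, no mean-variance trend, only the groups compared, a replicate block, and leaving out each library. Omission of small RNA genes and sex as a covariate were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.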

Results

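Gene expression was measured by RNA sequencing in 7 mouse lung libraries. Of these, 3 came from lung tumors of mice that overexpress EZH2 (OE tumors), 2 from lung labelled normal of EZH2-overexpressing mice (OE normal lung) and 2 from wild-type lung (WT lung). EZH2 is the histone methyltransferase of the Polycomb repressive complex PRC2, which silences developmental genes and the tumor suppressor locus Cdkn2a. Values are FPKM given as mean ± SD with n = 3 tumors, n = 2 OE normal lungs and n = 2 WT lungs, and each log2 difference is on the log2(FPKM + 1) scale with its standard error (SE) from limma, which understates the change of genes with low values. The labels do not state that replicates were separate animals, so p-values measure only the spread between these samples. Sex-linked genes differed within the tumors (tumor 1 male, tumors 2 and 3 female) and within the OE normal lungs (OE normal 1 male, OE normal 2 female), which places at least 2 animals in each of these groups and leaves this open for tumors 2 and 3 and for the WT lungs, both male. Between 12028 and 12625 genes reached 1 FPKM in the tumors, against 13203 to 13567 in the normal lungs. Read totals are not given in the sources used here, and the step size of low values placed the other libraries at 1.20 to 1.87 times the depth of tumor 1. Tumors 2 and 3 resembled each other more closely (Pearson r = 0.970 across genes, which are not independent replicates) than either resembled tumor 1 (r = 0.897 and 0.894), while r was 0.945 between the OE normal lungs and 0.959 between the WT lungs.

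The first question was how strongly Ezh2 was expressed in each group. Ezh2 stood at 18.2 ± 8.43 FPKM in the tumors, 10.8 ± 0.95 FPKM in OE normal lung and 3.15 ± 0.809 FPKM in WT lung. The group means differed 5.78-fold between tumors and WT lung and 3.44-fold between OE normal and WT lung. Tumor 1, at 8.48 FPKM, lay below both OE normal lungs (10.2 and 11.5 FPKM), while tumors 2 and 3 reached 23.5 and 22.6 FPKM. Ezh2 was higher in tumors than in WT lung in limma (log2 difference 2.10, SE 0.43, adjusted p = 0.0118). This call rested on both WT libraries, with adjusted p = 0.0515 in limma without WT 1 and 0.0887 without WT 2. The difference between OE normal and WT lung was 1.53 (SE 0.47, limma adjusted p = 0.406), and it passed when tumor 1 was left out of the shared estimate of the spread (limma adjusted p = 0.0388). Between tumors and OE normal lung the difference was 0.58 (SE 0.43, limma adjusted p = 0.329), and without tumor 1 it was 1.02 (limma adjusted p = 0.00219). Two-sided exact permutation tests of Ezh2 gave p = 0.2 for tumors against WT lung, p = 0.4 for tumors against OE normal lung and p = 0.333 for OE normal against WT lung. The smallest p these exact tests can give is 0.1 for 3 against 2 libraries and 0.333 for 2 against 2. Whether the transgene contributed reads to the deposited Ezh2 value is not stated.

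**Figure D1:**
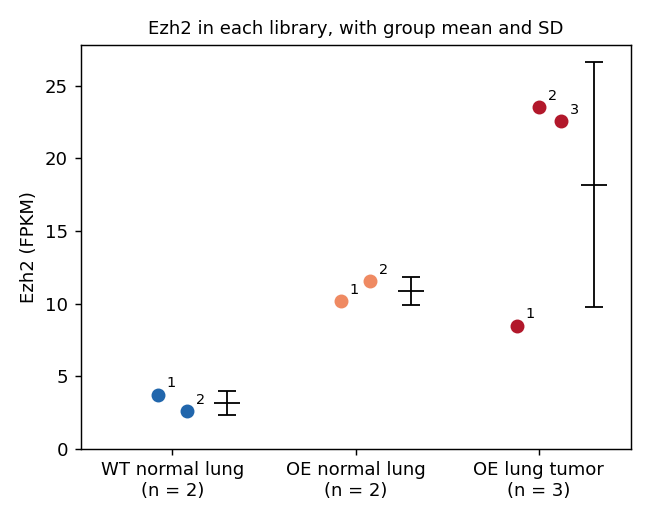
Ezh2 in FPKM (linear vertical axis from 0) for each of the 7 libraries, numbered by replicate, with the group mean (horizontal bar) and SD (error bars) beside the points. Tumor 1 at 8.48 FPKM sits below the OE normal lungs at 10.2 and 11.5 FPKM, and both WT lungs, at 3.72 and 2.58 FPKM, sit below all other libraries.

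The comparison of tumors with OE normal lung asked which genes distinguish EZH2-overexpressing tumors from lung of the same genotype. Tumors had higher levels of alveolar type 2 cell genes, of lung epithelial transcription factors and of transcriptional targets of ERK signaling. They had lower levels of genes of endothelium, ciliated cells, heart muscle, blood cells and the interferon response. Sftpd, a surfactant protein, was at 1762 ± 599.9 FPKM in tumors and 335 ± 39.3 FPKM in OE normal lung (log2 difference 2.34, SE 0.30), and the endothelial tight junction gene Cldn5 was at 4.77 ± 1.59 against 266 ± 57.7 FPKM (log2 difference -5.55, SE 0.25). The ERK-induced phosphatase Dusp4 was at 63.1 ± 14.5 against 3.39 ± 1.05 FPKM (log2 difference 3.86, SE 0.24).

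Of 11 alveolar type 2 genes tested, 7 rose in tumors and none fell, with the same number, 7, when adjusted over the list alone. The median log2 difference of this list was 1.66, and 1.68 without Sftpc. Sftpb, at 5466 ± 2428 against 1037 ± 407 FPKM, the phospholipid acyltransferase Lpcat1, at 306 ± 57.9 against 64.8 ± 29.2 FPKM, and the phosphate transporter Slc34a2, at 1092 ± 212 against 249.8 ± 98.3 FPKM, were among them (limma adjusted p = 0.0137, 0.00312 and 0.00370). Sftpc, the marker most specific to this cell type, was listed at 35944 FPKM in tumor 1 and at 0 in tumors 2 and 3, with 14320.5 and 10578 FPKM in the OE normal lungs and 15915 and 13050.0 FPKM in the WT lungs. Of 8 lung lineage and fetal regulators tested, 5 rose, and 6 when adjusted over the list alone, with a median of 1.76. The distal tip transcription factor Sox9 was at 19.6 ± 17.2 FPKM in tumors and 0.288 ± 0.0283 FPKM in OE normal lung (limma adjusted p = 0.00512), with 39.3 FPKM in tumor 1 and 11.97 and 7.68 FPKM in tumors 2 and 3. Id2 (log2 difference 2.78, SE 0.27), Foxa2 (1.86, SE 0.17) and the lung identity factor Nkx2-1 (1.76, SE 0.18) rose as well. In limma's camera test against all other genes, both lists were shifted upward with a preset correlation (adjusted p = 5.31e-04 and 9.93e-04). Neither call held with an estimated correlation (adjusted p = 0.437 and adjusted p = 0.455 with an estimated correlation).

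ERK pathway output genes also rose, 9 of 14 tested and 9 when adjusted over the list alone, with a median of 1.20 and none lower. Etv4, an ETS factor induced by ERK, was at 19.3 ± 7.41 against 0.303 ± 0.189 FPKM (log2 difference 3.91, SE 0.30), and the feedback inhibitors Spred1 and Spry1 differed by 3.25 (SE 0.15) and 1.79 (SE 0.19). The camera adjusted p was 3.33e-06 with the preset correlation, and adjusted p = 0.437 with an estimated correlation. Among 15 glycolysis and hypoxia genes, 6 rose and 1 fell, with the same numbers when adjusted over the list alone, and lactate dehydrogenase Ldha was at 447 ± 18.9 against 139 ± 12.2 FPKM (limma adjusted p = 4.37e-04). Of 13 ribosome biogenesis genes 3 rose, and 3 when adjusted over the list alone, led by the nucleolar proteins Nop58 (0.76, SE 0.17) and Npm1 (0.64, SE 0.15). Both lists passed camera with the preset correlation (adjusted p = 0.0139 and 0.0409), with adjusted p = 0.437 and adjusted p = 0.540 with an estimated correlation. Only Mcm7 (0.73, SE 0.14, limma adjusted p = 0.00989) passed among 31 cell cycle genes tested, and 0 passed when adjusted over the list alone. The cell cycle median was 0.11 as deposited and -0.09 after rescaling to TPM, while camera called the list upward in both (adjusted p = 0.0334 and 0.0355, and adjusted p = 0.612 with an estimated correlation as deposited).

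Genes of several other lung cell types fell together. All 14 endothelial genes tested fell (14 when adjusted over the list alone; median -2.81), including Tmem100 at 1.06 ± 0.294 against 222 ± 20.1 FPKM and the receptor gene Calcrl at 5.95 ± 0.796 against 176 ± 33.5 FPKM. All 14 ciliated cell genes fell (14 when adjusted over the list alone; median -3.30), including the ciliogenesis factor Foxj1 at 0.794 ± 0.901 against 40.6 ± 10.1 FPKM and Tppp3 at 9.67 ± 4.44 against 239.6 ± 0.337 FPKM. Among alveolar type 1 genes 7 of 12 fell and 1 rose (7 and 1 when adjusted over the list alone; median -1.33), with caveolin Cav1 at 24.7 ± 13.1 against 320.0 ± 35.1 FPKM and Hopx at 70.2 ± 14 against 344 ± 13.5 FPKM. Of 9 club cell genes other than Scgb1a1, 5 fell and none rose (median -2.87). Among the others Bpifa1 did not pass (limma adjusted p = 0.494), at 12907 and 15754 FPKM in tumors 2 and 3, 28.7 FPKM in tumor 1 and 449 and 216 FPKM in the OE normal lungs. With Scgb1a1 kept in the list, 6 of 10 fell and 1 rose when adjusted over the list alone. The gene that rose was Scgb1a1, so this call rests on its listing at 0. The club cell oxygenase Cyp2f2 was at 22.5 ± 10.7 against 1356 ± 372 FPKM. Scgb1a1 itself was listed at 2227, 56.3 and 1095 FPKM in tumors 1, 2 and 3 and at 0 in all 4 normal lungs. Smooth muscle and pericyte genes fell in 6 of 8 cases (6 when adjusted over the list alone; Cnn1 -3.40, SE 0.31), mesothelial genes in 5 of 5 (5 when adjusted over the list alone; Gpm6a -4.23, SE 0.35) and adipocyte genes in 5 of 6 (5 when adjusted over the list alone; Cfd -5.04, SE 0.55). Of 13 fibroblast and matrix genes, 4 fell and 1 rose (4 and 1 when adjusted over the list alone). Mfap4, a microfibril protein, was at 11 ± 12.8 against 280.3 ± 109 FPKM, and fibronectin Fn1 was at 109 ± 44.8 against 28.0 ± 0.0303 FPKM. Heart and striated muscle genes fell in 11 of 11 cases (11 when adjusted over the list alone; median -5.79), with the atrial myosin light chain Myl7 at 0.161 ± 0.187 against 249.7 ± 107 FPKM.

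Blood and immune genes followed in part. All 7 erythroid genes tested fell (7 when adjusted over the list alone; median -5.13), as did all 10 B and plasma cell genes (10 when adjusted over the list alone; median -3.99) and all 12 T and NK cell genes (12 when adjusted over the list alone; median -2.23). Cd79a, part of the B cell receptor, was at 0.911 ± 0.656 against 91.2 ± 74.2 FPKM, and the cytotoxic granule gene Gzma at 0.271 ± 0.228 against 6.85 ± 0.647 FPKM. Interferon response genes fell in 15 of 16 cases (15 when adjusted over the list alone; median -2.42), with Ifit3 at 2.10 ± 1.53 against 42.3 ± 12.9 FPKM and Oasl2 at 1.80 ± 1.11 against 26.2 ± 7.36 FPKM. Neutrophil genes fell in 4 of 7 cases (4 when adjusted over the list alone; S100a9 -3.28, SE 0.72). Macrophage genes did not follow, with 3 of 15 higher and 1 lower (3 and 1 when adjusted over the list alone; median 0.30), including matrix metalloproteinase Mmp12 at 23.5 ± 10.3 against 2.03 ± 0.460 FPKM and Trem2 at 19.3 ± 3.55 against 6.51 ± 0.0416 FPKM. Of 7 MHC class II genes, 1 rose (0 when adjusted over the list alone; H2-DMb1 0.89, SE 0.24). Camera with the preset correlation called the endothelial (adjusted p = 1.75e-09), ciliated (1.08e-08), heart (1.17e-06), interferon (4.79e-06), T and NK cell (6.07e-05), B cell (3.18e-04), erythroid (3.18e-04), adipocyte (0.00720), mesothelial (0.00725) and smooth muscle (0.00878) lists downward. These 10 calls were lost with an estimated correlation, where they gave adjusted p = 0.437 for endothelial, ciliated, interferon and T and NK cell genes, adjusted p = 0.455 for heart and erythroid genes, adjusted p = 0.504 for B cell genes and adjusted p = 0.533 for the remaining lists.

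PRC2 and EZH2-related lists moved in both directions. Of 11 PRC2 subunits, the EZH2 paralog Ezh1 (-0.78, SE 0.22) and Phf19 (-0.61, SE 0.14) fell and Mtf2 (0.42, SE 0.13) and Rbbp7 (0.37, SE 0.11) rose, with 2 lower and 2 higher when adjusted over the list alone. The sign of Phf19 turned to 0.12 under quantile normalization. Of 16 genes reported as repressed by EZH2, 3 rose and 5 fell, with the same numbers when adjusted over the list alone. Cdkn2a, which encodes the cell cycle inhibitor p16 and the p53 activator ARF, was at 32.5 ± 1.61 FPKM in tumors against 3.17 ± 1.23 FPKM in OE normal lung (log2 difference 3.04, SE 0.26, limma adjusted p = 5.54e-04). The metalloproteinase inhibitor Timp3 was at 68.6 ± 23.3 against 214 ± 31.8 FPKM. Among 9 developmental PRC2 targets above the expression minimum, 1 rose and 4 fell (2 and 5 when adjusted over the list alone). The T-box factor Tbx15 was at 13.4 ± 7.53 against 0.155 ± 0.10 FPKM, while Sox17 was at 2.03 ± 0.437 against 19.1 ± 3.48 FPKM and Meis2 at 0.525 ± 0.123 against 5.11 ± 0.720 FPKM. Of 24 insulin, IGF and PI3K-AKT components, 5 rose and 5 fell (5 and 5 when adjusted over the list alone), with Irs1 at 21.6 ± 13.6 against 2.35 ± 0.759 FPKM and the IGF-binding protein Igfbp2 at 4.07 ± 3.02 against 133 ± 1.10 FPKM. Irs1 was at 5.83 FPKM in tumor 1 and 29.3 and 29.5 FPKM in tumors 2 and 3.

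The smaller remaining lists gave few calls. Immediate early genes fell in 4 of 13 cases (4 when adjusted over the list alone), with Jun at 16.2 ± 6.59 against 73.2 ± 10.1 FPKM, and Fosb (-0.67, SE 0.16) turned to 0.10 under quantile normalization. Of 5 neuroendocrine genes, 3 fell and 1 rose (4 and 1 when adjusted over the list alone), the exception being Ddc at 6.92 ± 2.79 against 0.750 ± 0.0339 FPKM. Of 5 gastrointestinal genes, Gkn2 rose and Tff2 fell (1 and 1 when adjusted over the list alone), with Gkn2 at 381 FPKM in tumor 1 and 24.2 and 8.91 FPKM in tumors 2 and 3. The 2 basal and squamous genes above the expression minimum, Sox2 (-2.77, SE 0.16) and Ngfr (-0.67, SE 0.13), fell (2 when adjusted over the list alone), and Ngfr turned to 0.10 under quantile normalization. None of the 5 sex-linked genes passed (0 when adjusted over the list alone), and Xist was at 45 ± 39.4 against 32.2 ± 44.4 FPKM, with libraries high and low for it in both groups.

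Among called genes with non-overlapping groups and not listed at 0 in either group, the largest rises were in the imprinted genes Dlk1, at 699.8 ± 434 against 5.11 ± 6.82 FPKM, and Meg3, at 1163 ± 718 against 15.1 ± 14 FPKM, in the kininogen Kng2 (268 ± 121 against 1.94 ± 2.55 FPKM) and in the late cornified envelope gene Lce3f (268 ± 153 against 2.40 ± 3.29 FPKM). Their limma adjusted p-values were 0.00332, 0.00288, 9.54e-04 and 0.00226. All 4 were lower in tumor 1 (Dlk1 199.6 FPKM) than in tumors 2 and 3 (922 and 978 FPKM), and higher in OE normal 1 (Dlk1 9.94 FPKM) than in OE normal 2 (0.293 FPKM). Snord69, a small nucleolar RNA, passed as well (limma adjusted p = 0.0234), listed at 9056, 4101 and 4773 FPKM in tumors 1, 2 and 3, at 0 in both OE normal lungs and WT 1, and at 4036 FPKM in WT 2. The largest falls were in Myl7 (-7.70, SE 0.33), the cytochrome P450 gene Cyp2a5 (-7.40, SE 0.61), Actc1 (-7.09, SE 0.44), Tmem100 (-6.76, SE 0.16), Myl4 (-6.64, SE 0.41) and myoglobin Mb (-6.63, SE 0.46). Lce3f, Kng2, the hemoglobin genes and Cyp2a5 have close paralogs, whose reads the counting could have divided between copies.

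In total limma called 5350 of 14057 genes tested, 1844 higher and 3506 lower in tumors, of which 768 and 2426 differed by more than 1 on the log2 scale. The share of calls that were higher was 34.5% as deposited, 44.6% with median-of-ratios scaling (2541 higher and 3150 lower), 18.2% after rescaling to TPM (1085 and 4883) and 56.0% with quantile normalization (3390 and 2666). The median log2 difference over all genes tested was -0.11 as deposited and 0.05, -0.33 and 0.13 under these scalings. Without tumor 1 limma called 9604 genes, without OE normal 1 it called 3031 and without OE normal 2 it called 2877. With at least 1 library left out, the calls of Ezh1, Phf19, Mtf2, Rbbp7, Irs1, Mcm7, Nop58, Npm1, Mfap4, Gkn2, H2-DMb1, S100a9, Fosb, Sftpb and Snord69 were lost, as were the camera calls of the cell cycle list (without tumor 1, tumor 2 or OE normal 1), the ribosome biogenesis list (without tumor 1 or OE normal 1) and the adipocyte list (without tumor 1).

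**Figure D2:**
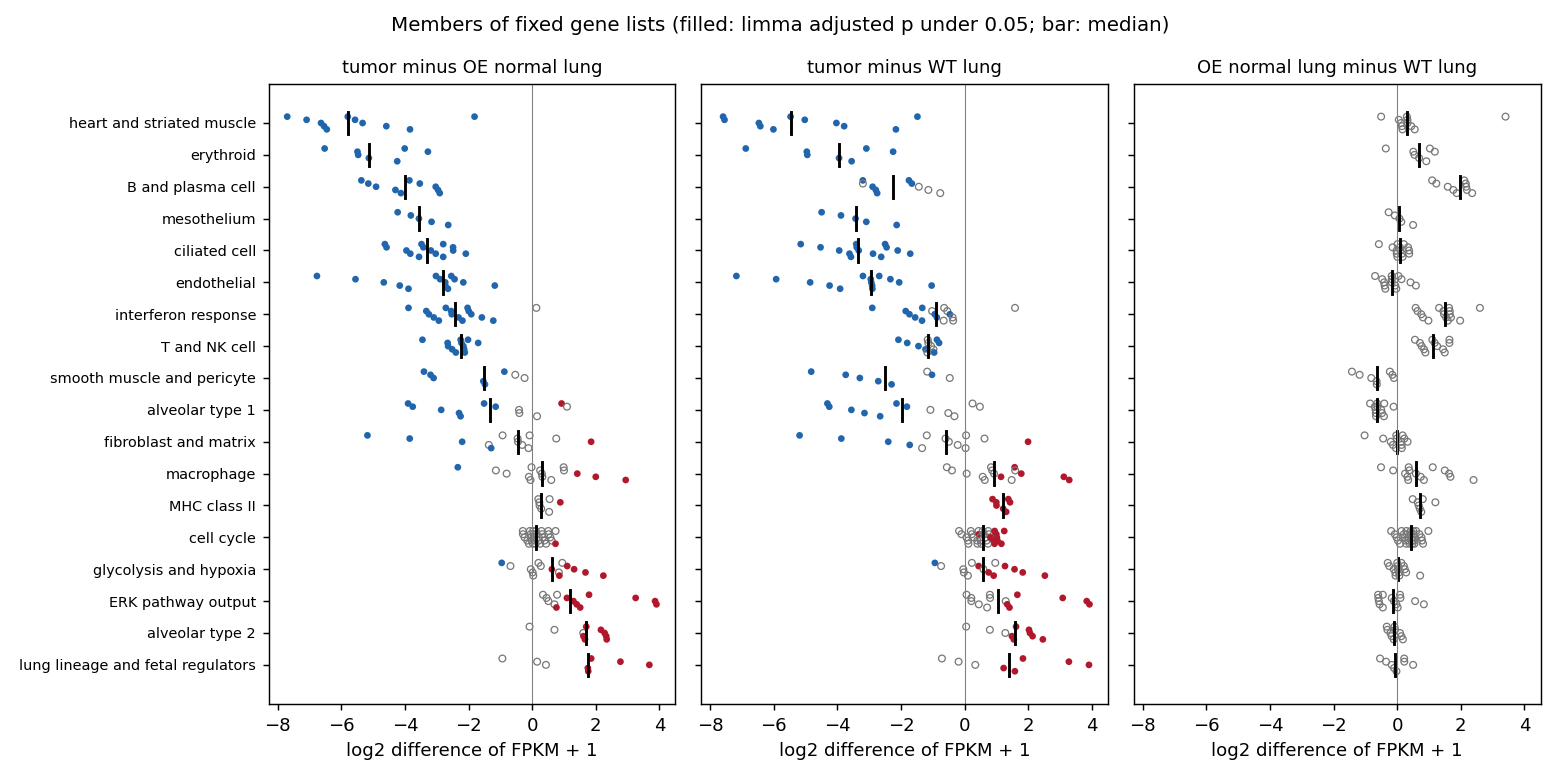
Log2 difference of FPKM + 1 (horizontal axis) for each member of 18 fixed gene lists in the 3 comparisons, leaving out Sftpc; filled points passed limma at an adjusted p under 0.05 and black bars are list medians. Endothelial and ciliated genes lie to the left in both tumor comparisons (medians -2.81 and -3.30 against OE normal lung), and all points for OE normal against WT lung are open.

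The comparison of tumors with WT lung asked which genes differ when the reference carries no transgene. Tumors again had higher alveolar type 2, lung lineage and ERK output genes and lower endothelial, ciliated, heart muscle and erythroid genes. In addition, MHC class II genes and part of the cell cycle genes were higher in tumors than in WT lung. Cd74, the invariant chain of MHC class II, was at 2303 ± 126 FPKM in tumors and 972 ± 401 FPKM in WT lung (log2 difference 1.31, SE 0.30), and the mitotic ubiquitin-conjugating enzyme Ube2c was at 10.2 ± 1.31 against 3.97 ± 2.17 FPKM (1.24, SE 0.28).

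All 7 MHC class II genes rose against WT lung (7 when adjusted over the list alone; median 1.21), including the class II transactivator Ciita at 15.5 ± 2.76 against 5.45 ± 3.11 FPKM. Of 31 cell cycle genes, 10 rose (8 when adjusted over the list alone; median 0.57), among them Bub1b, Cdk1 and Tk1 with log2 differences of 1.16, 1.03 and 1.01. Both sets of calls rested on WT 2, without which limma called 1 MHC class II gene and 1 cell cycle gene, and the calls of Cd74, Ciita, Ube2c, Bub1b, Cdk1 and Tk1 were lost. Macrophage genes rose in 5 of 15 cases (5 when adjusted over the list alone), with Mmp12 at 23.5 ± 10.3 against 1.39 ± 0.439 FPKM and the chitinase-like gene Chi3l3 at 771 ± 369 against 80.5 ± 17.3 FPKM. The median of the macrophage list over WT lung was 2.03 in tumor 1 and 0.67 and 1.01 in tumors 2 and 3. Camera called these 3 lists upward with the preset correlation (adjusted p = 0.00196, 6.67e-05 and 0.00403), and each had adjusted p = 0.440 with an estimated correlation. Alveolar type 2 genes rose in 7 of 11 cases (7 when adjusted over the list alone; Lpcat1 2.46, SE 0.33), lung lineage regulators in 5 of 8 (5 when adjusted over the list alone; Id2 3.28, SE 0.27) and ERK output genes in 6 of 14 (9 when adjusted over the list alone; Etv4 3.92, SE 0.30).

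All 14 endothelial and all 14 ciliated genes fell against WT lung (14 and 14 when adjusted over the lists alone; medians -2.94 and -3.36), and so did all 11 heart and striated muscle and all 7 erythroid genes (11 and 7 when adjusted over the lists alone). Alveolar type 1 genes fell in 7 of 12 cases (7 when adjusted over the list alone; Clic5 -4.31, SE 0.31). Interferon response genes fell in 9 of 16 cases (9 when adjusted over the list alone; median -0.91), T and NK cell genes in 7 of 12 (10 when adjusted over the list alone; median -1.15) and B and plasma cell genes in 6 of 10 (9 when adjusted over the list alone; median -2.25). None of 7 neutrophil genes passed (0 when adjusted over the list alone), and S100a8 was at 9.51 ± 5.48 against 7.81 ± 0.141 FPKM. Camera called 18 of 30 lists in this comparison with the preset correlation and 0 with an estimated correlation, where the smallest value was adjusted p = 0.440 with an estimated correlation. Of 11 PRC2 subunits 4 rose, among them Ezh2, its partner Jarid2 (0.91, SE 0.20) and Mtf2 (0.50, SE 0.13), and Ezh1 fell (-0.86, SE 0.22), with 4 and 1 when adjusted over the list alone. The calls of Ezh2, Jarid2, Mtf2 and Ezh1 were each lost without WT 1 and without WT 2, and those of Ezh1 and Mtf2 also without tumor 2, OE normal 1 or OE normal 2, and Ezh1 without tumor 3. Cdkn2a was at 32.5 ± 1.61 against 2.97 ± 1.27 FPKM (3.11, SE 0.26, limma adjusted p = 4.77e-04), while Timp3 fell to 68.6 ± 23.3 from 342 ± 42.6 FPKM.

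**Figure D3:**
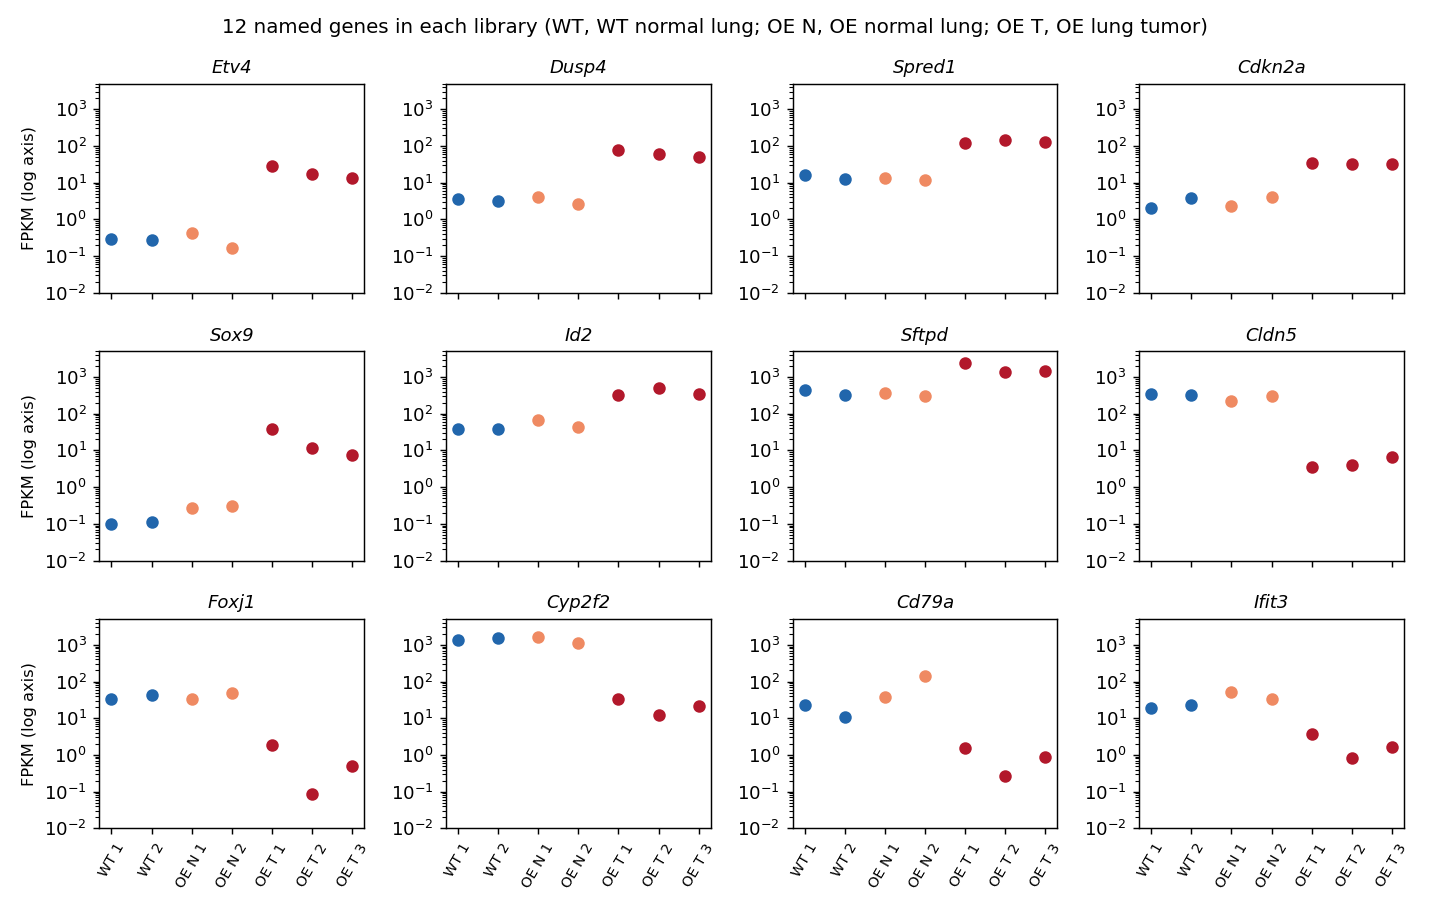
FPKM (log vertical axis) of 12 named genes in each library, with WT lungs in blue, OE normal lungs in orange and OE tumors in red. Cdkn2a lies between 31.3 and 34.3 FPKM in the 3 tumors and between 2.07 and 4.05 FPKM in the 4 normal lungs, and Cd79a reaches 144 FPKM in OE normal 2.

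Limma called 5371 genes between tumors and WT lung, 2115 higher and 3256 lower (39.4% higher), and the share that were higher was 54.7% with quantile normalization (3212 and 2662). Sex was partly confounded with this comparison. With sex as a covariate limma called 4246 genes (1602 higher and 2644 lower). In that fit 15 named genes lost their calls, among them Cd74, Ciita, Ube2c and Bub1b. Both WT lungs were male, so the sex term rests on tumor 1 against the other tumors and on the OE normal lungs. It may therefore also take up other differences of tumor 1. The median log2 difference over all genes tested was -0.06 as deposited, -0.16 after rescaling to TPM and 0.11 with quantile normalization. Among genes not listed at 0 in a whole group, the largest rises were again in Dlk1 (8.54, SE 1.06), Kng2 (7.62, SE 0.68), Lce3f (7.55, SE 0.86), Meg3 (6.76, SE 0.87) and Rian (6.75, SE 0.82), the last a noncoding RNA of the same imprinted locus as Dlk1 and Meg3. Both tumor comparisons shared 1566 higher and 2818 lower calls, and 3 genes were called in opposite directions. Independent lists would share 277 and 812 and simulated unchanged groups shared 0, but the first value leaves out the shared tumor libraries and the second any effect, so neither measures a shared effect. Across genes the 2 sets of log2 differences had r = 0.914, against 0.397 in simulated unchanged groups that share the tumor libraries, and a covariance of 1.22 against 0.0504. Part of this excess may come from the shared tumor libraries, since 3 libraries cannot be split into sets of 2 each. The camera calls of the B cell and ribosome biogenesis lists were lost without tumor 1. Without tumor 1 limma called 9429 genes, without WT 1 it called 2701 and without WT 2 it called 2411.

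The comparison of OE normal with WT lung asked how lung of overexpressing mice outside tumors differs from WT lung. Sex was partly confounded here too, since OE normal 2 was female and OE normal 1 and both WT lungs were male. Differences can therefore not be assigned to EZH2 alone. No gene passed the adjusted threshold, and several lists of immune genes had positive median differences. Interferon response genes had a median log2 difference of 1.5, B and plasma cell genes 1.99 and T and NK cell genes 1.14. Ifit3, an interferon-induced gene, was at 42.3 ± 12.9 FPKM in OE normal lung and 20.5 ± 2.97 FPKM in WT lung (0.98, SE 0.46, limma adjusted p = 0.658), and the B cell receptor component Cd79b was at 94.8 ± 70.8 against 17.8 ± 8.16 FPKM (2.19, SE 0.90, limma adjusted p = 0.583). Hopx, an alveolar type 1 factor, was at 344 ± 13.5 against 625 ± 86.8 FPKM (-0.85, SE 0.22, limma adjusted p = 0.314).

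Limma called 0 of 14057 genes, with 1208 at an unadjusted p under 0.05 and a smallest adjusted p of 0.102, and no other tool was run. The median log2 difference over all genes tested was 0.02 as deposited and 0.15 after rescaling to TPM. Among genes with non-overlapping groups and a higher mean of at least 5 FPKM, the 10 with the smallest unadjusted p did not pass. Their separation between the groups was a condition of the choice. They included the myeloid genes Clec12a (10.1 ± 0.415 against 2.87 ± 0.0415 FPKM) and Wfdc17 (33.8 ± 7.32 against 4.65 ± 1.46 FPKM), and the B cell factor Pou2f2 (8.79 ± 2.00 against 1.27 ± 0.521 FPKM). Rprml (1.73 ± 0.163 against 8.40 ± 1.29 FPKM) and the guanylate-binding protein Gbp2b (0.317 ± 0.210 against 6.01 ± 1.17 FPKM) had lower values in OE normal lung. Cyp4f18, Nfkbid, Gm7609 and Snora70, the last listed at 0 in both WT lungs, also belonged to this set. In simulated data for this comparison limma recovered 36.2% of genes changed 2-fold, 88.3% of genes changed 4-fold and 96.5% of genes changed 8-fold. The simulated changes were in better expressed genes with equal spread in all groups, which these data need not have. Large changes can therefore have been missed here, and Wfdc17 and Pou2f2 did not pass.

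Adjusted over the list alone, 11 of 16 interferon response genes, 7 of 10 B and plasma cell genes, 6 of 12 T and NK cell genes, 5 of 6 adipocyte genes and 4 of 7 neutrophil genes were higher in OE normal lung, against 0 in each when adjusted over all genes. Camera called these 5 lists upward with the preset correlation (adjusted p = 3.69e-15, 1.97e-07, 8.06e-09, 1.13e-06 and 6.35e-05). With an estimated correlation all 5 calls were lost, and the interferon list had adjusted p = 0.30 with an estimated correlation. The libraries differed in which lists stood out. Over WT lung, the B cell median was 1.25 in OE normal 1 and 2.72 in OE normal 2, the neutrophil median was 2.13 and 0.96, and the interferon median was 1.64 and 1.32. S100a8, a neutrophil granule gene, was at 92.0 FPKM in OE normal 1 and 24.0 FPKM in OE normal 2. Macrophage (median 0.59), MHC class II (0.71), cell cycle (0.43) and erythroid (0.69) genes were also called upward, and alveolar type 1 (-0.62), smooth muscle (-0.65), neuroendocrine (-0.20) and EZH2-repressed genes (-0.40) downward, with the preset correlation only (smallest adjusted p = 0.30 with an estimated correlation). The macrophage and erythroid calls were lost without OE normal 1 and the neuroendocrine call without OE normal 2. Adjusted over the list alone, 2 alveolar type 1 genes and 1 smooth muscle gene were lower. None of the 11 PRC2 subunits passed, Ezh2 included (0 when adjusted over the list alone), with Rbbp7 at 40.2 ± 2.32 against 38.6 ± 1.79 FPKM. Without tumor 1, which lies outside this comparison but enters the shared estimate of the spread, limma called 302 genes, 214 higher and 88 lower, among them 4 interferon response and 3 macrophage genes.

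A last comparison asked whether OE normal lung was shifted from WT lung in the direction of the tumors. Across 14057 genes the covariance of the 2 sets of log2 differences was 0.111, against 0.0771 on average (0.0602 to 0.0947) in 50 simulations of unchanged groups that share the WT libraries. The correlation was r = 0.201 against 0.552 in those simulations, and genes are not independent replicates. Those simulations hold no tumor effect, and large tumor differences can lower r even where OE normal lung is shifted. The gap in r therefore does not bear on a shift. The simulations also use the spread shared with the tumors, while the WT libraries' own spread gave a covariance of 0.0606. The excess covariance turned negative without OE normal 1, where the covariance fell to 0.0759, and without WT 2. Without WT 2 the covariance itself rose to 0.126. The excess turned negative there because the reference calculated from the shared spread rose to 0.160. OE normal 1 also held low levels of genes restricted to tumors 2 and 3, described below. Endothelial and ciliated genes, which fell in both tumor comparisons, had medians of -0.17 and 0.09 between OE normal and WT lung, and Etv4 was at 0.303 ± 0.189 against 0.282 ± 0.0142 FPKM. Interferon, B cell, T and NK cell, erythroid and adipocyte genes had positive medians here and negative medians between tumors and WT lung. Other lists had the same sign in both, given here with OE normal lung first. Alveolar type 1 (-0.62 and -1.98) and smooth muscle genes (-0.65 and -2.51) were negative. Cell cycle (0.43 and 0.57), macrophage (0.59 and 0.92) and MHC class II genes (0.71 and 1.21) were positive. The shared WT libraries by themselves move both differences the same way.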

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

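The omission of small RNA genes and the sex covariate were chosen after the data were seen, and all other alternatives before. Each library left alone in its group by an omission was assumed to vary like the other groups. Limma calls between OE normal and WT lung rose from 0 (1208 at an unadjusted p under 0.05) to 1 with a pseudocount of 0.1, 2 without a filter on low values, 3 with only the groups compared and 1 with sex as a covariate. With each library left out in turn they ran from 0 to 302, the highest without tumor 1. Calls ran from 2877 (without OE normal 2) to 9604 (without tumor 1) between tumors and OE normal lung, where 5338 of the 5350 genes were called again without tumor 1, and from 2411 (without WT 2) to 9429 (without tumor 1) between tumors and WT lung. Of named genes, 85 of 116 calls against OE normal lung and 81 of 118 against WT lung held in all 7 omissions, and none changed sign. These counts of named genes leave out Ezh2, which is given apart. Over the omissions the Ezh2 log2 difference ran from 0.34 to 1.02 for tumors against OE normal lung, 1.86 to 2.55 against WT lung and 1.33 to 1.73 for OE normal against WT lung, and with sex as a covariate it was 0.44, 1.54 and 1.11. Deviations from group means gave no sign of pairing by replicate number (correlations between -0.0341 and 0.0341), but this cannot exclude shared animals. By sex-linked genes tumor 1 and OE normal 1 were both male and tumor 2 and OE normal 2 both female, so pairing stays open. With the replicate block limma called 3130, 2999 and 1 genes in the 3 comparisons and 4278 between tumors and all normal lung, and the Ezh2 difference between tumors and WT lung was 1.89 (limma adjusted p = 0.0502). Camera called 16, 18 and 13 lists at the preset correlation and 0, 0 and 0 with an estimated correlation, which widens the null by construction where members vary together. For tumors against OE normal lung, list calls were also lost with the 5 FPKM filter (2, cell cycle and ribosome biogenesis), quantile normalization (2, glycolysis and ribosome biogenesis), TPM (1, ribosome biogenesis) and sex as a covariate (1, cell cycle). For OE normal against WT lung they were lost with a pseudocount of 0.1 and with TPM (1 each, erythroid) and with sex as a covariate (2, erythroid and neuroendocrine), and for tumors against WT lung 0 were lost in these settings. The excess covariance of OE normal lung along the tumor change was 0.0347, 0.0588 with sex as a covariate, and -0.0334 (without WT 2) to 0.0660 (without OE normal 2) over the omissions, with -0.00249 without OE normal 1. Here the reference was calculated from the shared spread in each setting (0.0763 as deposited, 0.160 without WT 2), in place of the simulated mean of 0.0771. For tumors against OE normal lung, the cell cycle median was -0.0890 after rescaling to TPM, and quantile normalization gave 0.12 for Phf19, 0.10 for Ngfr and 0.0977 for Fosb (limma adjusted p = 0.561, 0.525 and 0.615). The cause of the other changes was not tested. Taking the row with the highest mean in place of a sum was not run, since no symbol repeats.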

Other observations

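List medians relative to WT lung in tumors 1, 2 and 3 were -2.88, -3.19 and -3.00 for endothelial genes, 0.26, -1.96 and -0.65 for fibroblast genes and -2.30, -4.40 and -3.62 for mesothelial genes, and differences among the tumors were not tested. Among single genes, the mesenchymal receptor Pdgfra in tumor 1 was at 17.3 FPKM against 2.45 and 3.20 FPKM in tumors 2 and 3, and the lysosomal macrophage gene Cd68 at 58.5 against 20.2 and 26.9 FPKM. The prolyl hydroxylase Egln3, a target of hypoxia signaling, was at 2.80 FPKM in tumor 1 against 13.9 and 16.0 FPKM. The glycolytic enzymes Eno1 and Hk2 were higher in all 3 tumors than in each normal lung, with log2 differences of 1.10 and 1.32 against OE normal lung, and both lost that call with at least 1 library left out, Hk2 also after rescaling to TPM (1.18). Among macrophage genes Cd5l was at 0.257 ± 0.161 FPKM in tumors and 0.197 ± 0.0307 FPKM in WT lung, and at 10.0 and 2.61 FPKM in the OE normal lungs, so it passed in limma against OE normal lung (adjusted p = 0.00875) and not against WT lung (adjusted p = 0.924).

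Tests on the 3 patterns below were chosen after the results were seen, except the count of splits. Of the 35 splits of the 7 libraries into 3 and 4, 1, the real one, called as many genes as tumors against all normal lung (6645), and the highest other split called 6 (tumors 2 and 3 with OE normal 2). With 35 splits the smallest share possible is 1 of 35. Every other split put tumors and normal lungs in the same group, which widens the spread and lowers the calls. The count therefore cannot exclude chance by itself, and whether the libraries are separate animals is not stated.

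Genes of many cell types were lower in tumors than in OE normal lung. If tumor cells had diluted every other cell type alike and expressed none of the listed genes, FPKM ratios would be alike over their lists. The ratios were compared among 7 lists with at least 5 genes at 10 FPKM or more in OE normal lung. Of 21 pairs, 14 had interquartile ranges that did not overlap (13 to 16 with each tumor or OE normal library left out). Equal dilution as the whole cause is therefore argued against. The median log2 ratio was -3.01 (quartiles -4.26 to -2.62) for endothelial and 0.32 (-0.15 to 0.99) for macrophage genes. For endothelial genes, scaling of the libraries as the whole cause is also argued against, since their highest median under the 3 scalings was -2.65. Median-of-ratios size factors ran only from 0.894 (tumor 3) to 1.07 (OE normal 2), so a small shift was fixed in advance. Lists with smaller differences, such as fibroblast genes, are not covered by this. Unequal loss of cell types, how the tissue was taken, and culture of nodules, which the labels mention, may each contribute and were not tested.

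Genes with at least 20 FPKM on average in tumors 2 and 3 and at most 0.2 FPKM in WT lung appeared at low levels in OE normal 1, and some of them, such as Scgb1a1 (2227 FPKM), were also expressed in tumor 1. Of 11 such genes, 81.8% had a ratio within 2-fold of the median of 1.20% (quartiles 1.03 to 1.44), Scgb1a1 among the exceptions at 0, and 4 of the 11 are Cyp2c paralogs that share reads. A change common to both overexpressing lungs is argued against, since the median ratio over these genes was 0.0355% in OE normal 2, and 10 of the 11 had a lower ratio there than in OE normal 1 (Scgb1a1 was at 0 in both). A small share of RNA from tumors 2 or 3, or from tissue like them, is a candidate explanation, as are early tumor cells in that lung, and the OE normal means of Dlk1, Meg3, Kng2 and Lce3f (ratios of 1.05%, 1.59%, 1.11% and 1.33%) may include it. Xist in this male library was at 0.816 FPKM, 4.90 SDs above the mean of 3 other male libraries. RNA of tumors 2 and 3 at the median ratio of 1.20% would place it at 1.01 FPKM. The 3 libraries are too few to say whether RNA of a female animal was present.

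Sftpc was listed at 0 in tumors 2 and 3, and Scgb1a1 at 0 in all 4 normal lungs. The other alveolar type 2 genes had a median log2 difference of 2.00 between tumors 2 and 3 and the normal lungs (10 of 10 higher), and the other club cell genes had a median of 2.49 between normal lungs and tumors (7 of 9 higher). Both directions go with an estimate that was withheld at a very abundant gene. The comparisons above had already shown them, so this check could hardly have failed. It cannot tell a withheld estimate from a true absence of the transcript. Among 14 other genes with at least 1000 FPKM in every normal lung, the lowest share left in tumors 2 or 3 was 0.873% (Cyp2f2). A true loss of Sftpc transcripts in tumors 2 and 3 stays open, since no read counts are at hand.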
